A study of Homo sapiens with 4 samples.

How the data were processed

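RNA was measured by RNA-seq in 4 libraries of H9 cells on day 5 of cardiac differentiation, 2 from WT and 2 from SMYD1_KO cells. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a SMARTER kit for mRNA. The authors deposited 1 table of FPKM values (reads or fragments per kilobase of exon, scaled to depth) with 1 column per library for 33142 genes, together with gene symbols, biotypes, positions and annotation terms. The aligner, the counter, the strand setting and the annotation are not given in the sources used here. Per the submitters' processing notes the genome builds were GRCm38 and mm10, which are mouse builds. All 33142 gene identifiers of the deposited table are human Ensembl identifiers, and of those shared with GENCODE 29, 95.6% had positions identical to it on GRCh38. Human GRCh38 positions are therefore printed as the table gives them. Columns were matched to libraries by their names, and groups were taken from the sample titles.

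The deposited FPKM values were found to be whole reads divided by exon length and depth. With union exon lengths from GENCODE 29, or a nearby whole length where that failed, whole reads were recovered for 100% of genes within a tolerance of 0.01 reads. The first lengths alone gave 94.4% of values. The recovered depths were 18184604 and 17621360 reads in WT and 17592796 and 16886870 reads in SMYD1_KO. The denominators of the FPKM values were slightly lower, so that 1 read in a gene of 1 kb is worth 0.056 to 0.06 FPKM. Low genes are therefore measured with few reads, and a fold change on log2(FPKM + 1) understates their change. Fold changes given as folds are ratios of mean FPKM, and by a rule added after the values were seen the ratio is not printed for named genes in which leaving out 1 library moved it by over 1.5 times. Fold changes given as log2 are on log2(FPKM + 1). Where a group had 0 reads in both libraries, the fold was computed against a floor of 3 reads per library.

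The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1) for the 13902 genes with a mean of at least 1 FPKM over the 4 libraries, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each adjusted p printed for a gene comes from it unless an alternative is named. Since FPKM values are not counts, a count model was not the main test; voom from limma on the recovered reads, with trimmed mean scaling (TMM), was an alternative. Exact permutation of 2 against 2 libraries has 3 possible splits and cannot give a p below 0.33, so calls rest on the spread shared across genes. The script was tested on simulated data, made from the real means and depths for 13890 genes with a dispersion of 0.005. At 2-fold it recovered 72.9% of changed genes, at 4-fold 97.9%, at 1.5-fold 20% and at 1.25-fold 0%. Of the calls, 10.8% were unchanged genes. Only 47 to 50 genes were changed at each fold, whereas 49.8% of tested genes were called in the real data. The adjusted threshold was therefore stricter in the simulation, and the recovery rates do not describe the real comparison. The 10.8% of unchanged calls lay above the threshold of 0.05, which a stricter cutoff does not explain, so the nominal rate may not be kept. Replicates were compared before averaging. The chi-square per gene of recovered reads was 5 between the WT libraries and 3.51 between the SMYD1_KO libraries, above sampling noise, against 132 between WT replicate 1 and SMYD1_KO replicate 1. On log2(FPKM + 1) the Pearson correlation across genes, which are not independent replicates, was at least 0.987 within groups and at most 0.859 between groups, and the first principal component held 91.9% of the variance.

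Before the data were examined, 26 gene lists, the design, the alternatives and the rule for named genes were fixed. The rule takes SMYD1, the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap, up to 4 called members of each list with the largest changes, and 4 pathway components, among them GSK3B, CTNNB1 and MAPK3. Some genes that the rule takes are not reported here. Several, but not all, genes that make up a count of 5 or fewer are named as well, after their values were seen. The 21 lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists. At that setting genes of a set are compared with the other genes, so genes and not libraries are the units of the test. Camera with an estimated correlation and fry were alternatives. With an estimated correlation no list passed, but camera then has only the few residual degrees of freedom of 4 libraries. A list can then hardly pass, so those adjusted p-values cannot decide whether a shift is absent. The lists covered cardiac progenitor, early mesoderm, cardiomyocyte, endothelial, smooth muscle and stroma, endoderm and pluripotency genes, targets of Wnt, ERK, BMP, retinoic acid and p53 signalling, pathway components, cell cycle phases, CDK inhibitors, the SMYD family, stress, hypoxia, mitochondrial and ribosomal genes. Annotation terms with 10 to 500 tested genes were tested with camera, adjusted per source. Medians of autosomes were compared by camera, adjusted over chromosomes. A further 5 lists, and tests by chromosome arm, were added after the first results and are used in the closing part and for 1q. The list test of 1 of these, of HOX genes, was set aside because it holds HOXB1, seen before it was written.

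The analysis departed from the plan in these points. SMYD1 was fitted although it lay below the filter, outside the adjusted set. Genes of the Y chromosome and XIST are not named or tabulated, and the comparison by chromosome was limited to autosomes. The other alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, TMM, upper quartile and quantile scaling, eBayes without trend or with robust fitting, the replicate number as a block, each library left out, a 2-fold minimum, an adjusted p under 0.1, a one-sided Fisher's exact test for terms, and, added later, the tested genes outside 1q. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.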

Results

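RNA-seq libraries were made from H9 cells, an established human embryonic stem cell line, on day 5 of a differentiation towards cardiomyocytes, the stage the submitters call cardiac progenitor. Wild-type cells (WT, n = 2 libraries) were compared with cells in which SMYD1 had been disrupted by CRISPR/Cas9 editing (SMYD1_KO, n = 2 libraries). SMYD1 is a histone methyltransferase restricted to heart and skeletal muscle. The series title names proliferation of cardiac progenitors and signalling through GSK3β, β-catenin and ERK. The comparison therefore asks which progenitor, proliferation and signalling genes differ once SMYD1 is disrupted. Depths recovered from the deposited values were 18184604 and 17621360 reads in WT and 17592796 and 16886870 reads in SMYD1_KO. At the depths by which the FPKM were scaled, which are slightly lower, 1 read in a gene of 1 kb was worth 0.056 to 0.06 FPKM. The labels do not say whether the 2 libraries of a group came from separate cultures. The limma p-values of genes therefore measure only the spread between these libraries, which may be technical. Camera p-values at the preset correlation treat genes, not libraries, as the units, and do not measure that spread. Intervals and floors cover counting error only.

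SMYD1 (ENSG00000115593, GRCh38 chromosome 2, 88067780 to 88113387, plus strand) was measured first as a check of the labels. It stood at 0.659 and 0.592 FPKM in the WT libraries, from 54 and 47 reads, and at 0 in both SMYD1_KO libraries. Against a floor of 3 reads per library it was at least 16.2-fold lower in SMYD1_KO. The log2 fold change on log2(FPKM + 1) was -0.70 with an SE of 0.148 and an unadjusted limma p of 0.00495. That value depends on the pseudocount, at -1.17 with 0.5, -2.86 with 0.1 and -6.63 with voom on recovered reads, all lower in SMYD1_KO. The gene lay below the filter of a mean of 1 FPKM and was therefore kept out of the counts of called genes. TBX5, a transcription factor of the heart field, had 86 reads over the WT libraries and also 0 in SMYD1_KO. Reads of 0 therefore do not separate an edited locus from a gene that was not expressed. Of the SMYD family, SMYD3, which lies on 1q as does SMYD2, and SMYD4 were higher in SMYD1_KO, and SMYD2 and SMYD5 did not pass the test, with a list median log2 fold change of 0.17 (camera adjusted p = 0.539). The calls of SMYD3 and SMYD4 were each lost on leaving out SMYD1_KO replicate 1 (adjusted p = 0.0598 and 0.14) or SMYD1_KO replicate 2 (adjusted p = 0.0965 and 0.0942), and that of SMYD4 also without WT replicate 1 (adjusted p = 0.095) or WT replicate 2 (adjusted p = 0.0583). Both were also lost without the expression filter (adjusted p = 0.0702 and 0.0505).

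The genes with the largest increases in SMYD1_KO on log2(FPKM + 1) included FZD5, a Wnt receptor, at 2.60 ± 0.117 FPKM in WT and 348.2 ± 11.02 in SMYD1_KO (SD, n = 2 each). FZD5 lies on chromosome 2 from 207762586 to 207769563. HHEX, a transcription factor of the anterior endoderm, went from 2.06 ± 0.258 to 93.0 ± 1.19 FPKM, and CYP26A1, which breaks down retinoic acid, from 13.7 ± 0.642 to 361.4 ± 8.46 FPKM (SD, n = 2 each). The chemokine receptor gene CXCR4 was 21.9-fold higher. ACTA1, skeletal muscle α-actin, was 72.5-fold higher, and CD34, a surface glycoprotein, went from 16 and 6 reads in WT to 4350 and 3978 reads in SMYD1_KO. Both lie on the long arm of chromosome 1 (1q), where most genes were higher in SMYD1_KO. The median log2 fold change of 1q was 0.495, far below that of ACTA1 (6.05) and CD34 (4.70). Also among the largest increases were RP11-14D22.1 and the short RNA loci Six3os1_1, Six3os1_2 and Six3os1_5. Those 3 loci lie beside SIX3, and their reads may not be separable from neighbouring transcripts because the strand setting of the counting is not given in the sources used here.

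On log2(FPKM + 1) the largest decrease among called genes was that of HAPLN1, a hyaluronan-linking protein of the cardiac extracellular matrix, from 166.9 ± 14.4 to 1.62 ± 0.218 FPKM (SD, n = 2 each; chromosome 5, 83637805 to 83721613). By the ratio of FPKM, HAPLN1 was 102.9-fold and IGF2, a growth factor, 150.2-fold lower, and APLNR, the apelin receptor of cardiac mesoderm, went from 607.5 ± 26.6 to 11.5 ± 0.163 FPKM (SD, n = 2 each). HOXB2 went from 1585 and 1535 reads in WT to 4 and 13 in SMYD1_KO, and NKX2-6 from 482 and 497 reads to 12 and 3. LIX1 was 66.3-fold, LCP1 37.8-fold, SPP1 32.4-fold and ERVH48-1 46.9-fold lower. The pseudogene MTCO1P12 fell 62.5-fold, an uncertain value of untested cause, because its sequence is nearly identical to the mitochondrial gene MT-CO1, which stood at 7137 FPKM in WT and 6675 FPKM in SMYD1_KO and did not pass the test (adjusted p = 0.45). Across 13902 tested genes, limma called 6922 at a Benjamini-Hochberg adjusted p under 0.05. Of these, 3613 were higher and 3309 lower in SMYD1_KO, and 1925 also changed at least 2-fold (1029 higher, 896 lower). Which direction held more calls depended on the scaling, with 3164 higher and 3798 lower with upper quartile scaling and 3446 higher and 3571 lower with quantile normalization. Lower genes were also the more numerous without genes of 1q, at 3216 against 3172 higher. Groups did not overlap in 76.1% of tested genes, where chance gives 33.3%. The count of called genes fell to 4602 without SMYD1_KO replicate 1, and the count of lower genes to 2176 without SMYD1_KO replicate 1 and to 2171 without SMYD1_KO replicate 2.

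Cardiac progenitor genes moved in both directions. Of 13 tested members, 9 fell, 3 rose and 1 did not pass the test, with the same counts adjusted over the list alone. HAND1, a transcription factor of the first heart field, fell from 675.4 ± 34.1 to 36.1 ± 2.03 FPKM (SD, n = 2 each; log2 fold change -4.19, SE 0.067, limma adjusted p = 7.75e-06). PDGFRA, a surface receptor of cardiac mesoderm, fell 34.2-fold and the ligand gene BMP4 13.9-fold. HAND2 went from 472 and 482 reads in WT to 6 and 12 in SMYD1_KO. The 3 members that rose are named because they are so few, after their values were seen. They were NKX2-5, a core cardiac transcription factor, from 2.21 to 18.9 FPKM, ISL1, a marker of the second heart field, from 19.8 to 47.1 FPKM, and GATA4 from 37.2 to 62.3 FPKM. The list had a median log2 fold change of -1.29 (camera adjusted p = 0.0104, and adjusted p = 0.455 with an estimated correlation). The call was lost among genes with a mean of at least 5 FPKM (adjusted p = 0.153), and without the filter the median was -0.64. In the same libraries all 10 tested endoderm markers were higher, with a median log2 fold change of 3.20.

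**Figure D1:**
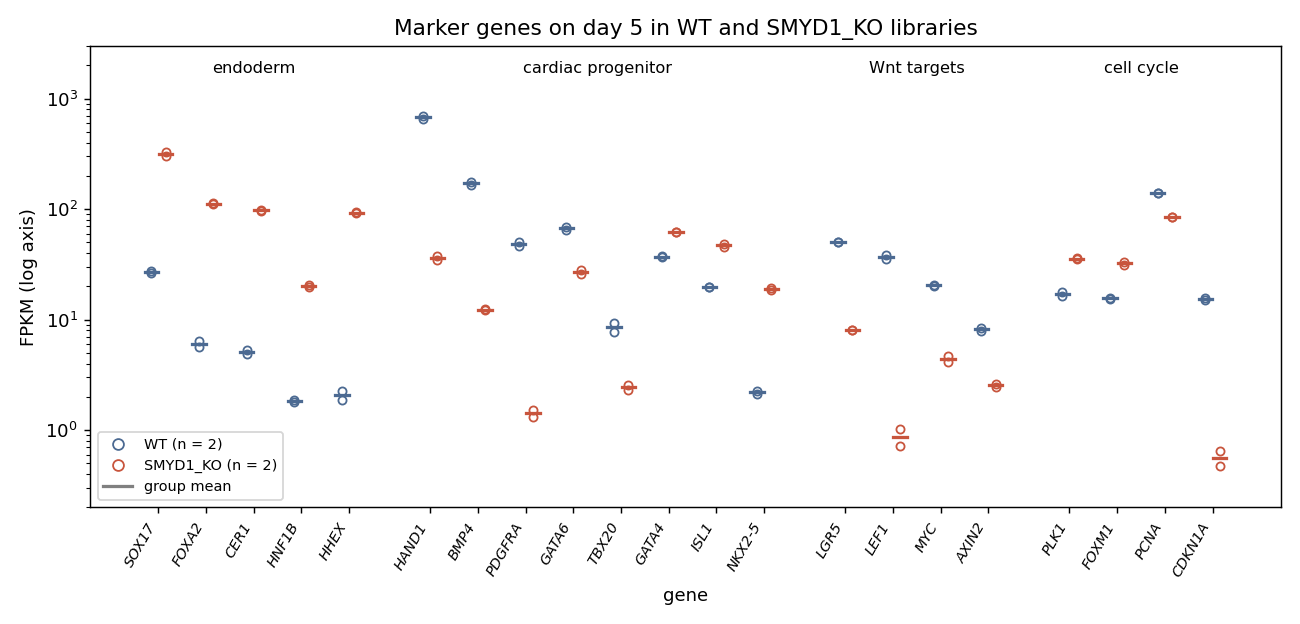
FPKM on a log axis of marker genes in each WT (blue, n = 2) and SMYD1_KO (red, n = 2) library, where circles are libraries and lines are group means; genes were picked to illustrate the lists after their values were seen. HAND1 lies at 675.4 FPKM in WT and 36.1 FPKM in SMYD1_KO, while FOXA2 lies at 6.08 and 112.2 FPKM.

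Early mesoderm genes were split, with 6 of 11 tested members lower, 4 higher and 1 not called, also adjusted over the list alone. MIXL1, which lies on 1q, fell 7.51-fold, MESP2 fell 9.64-fold and DLL3 8.71-fold. GSC, a gene of the organizer and anterior mesendoderm, rose from 0.181 ± 0.0678 to 14.01 ± 0.272 FPKM (SD, n = 2 each). The list median log2 fold change was -0.79 (camera adjusted p = 0.539), but -0.24 without genes of 1q, -0.07 without the expression filter and 0.66, of opposite sign, with a mean of at least 5 FPKM. Contractile and other cardiomyocyte genes were also split, with 7 of 14 tested members lower, 5 higher and 2 not called, the same adjusted over the list alone. ACTC1, cardiac α-actin, rose 8.96-fold to 337.3 ± 2.38 FPKM (SD, n = 2), whereas the intermediate filament gene DES fell 8.79-fold, MYL4 5.63-fold and MYH6 13.2-fold. The median log2 fold change of the list was -0.25 (camera adjusted p = 0.539), but of opposite sign at 0.11 without genes of 1q and 0.21 with a mean of at least 5 FPKM.

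Markers of definitive and later endoderm were higher in SMYD1_KO in all 10 tested members, also adjusted over the list alone. Below the filter, AFP stood at 0.15 FPKM in both groups, and ALB and SERPINA1 had at most 3 reads in a library. TTR, also below it, went from 0 FPKM in WT to 1.13 FPKM in SMYD1_KO. CER1, a secreted Nodal and BMP antagonist, rose from 5.14 ± 0.28 to 97.7 ± 0.856 FPKM and FOXA2, a pioneer factor of the endoderm, from 6.08 ± 0.522 to 112.2 ± 1.18 FPKM (SD, n = 2 each; limma adjusted p = 7.75e-06 and 7.80e-06). FOXA1 rose 43.9-fold, and APOA2, which lies on 1q, rose 16.6-fold. The list had a camera adjusted p of 2.07e-07, and adjusted p = 0.455 with an estimated correlation. Its median log2 fold change was 2.90 without genes of 1q and 1.97 without the expression filter.

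Of 11 endothelial genes only 4 were tested, of which 3 were lower, and 4 adjusted over the list alone. PECAM1 and CDH5, below the filter, stood at 0.048 and 0.268 FPKM in WT and at 0.046 and 0.203 FPKM in SMYD1_KO. KDR, a VEGF receptor also present on cardiac mesoderm, fell from 105.9 ± 1.12 to 13.5 ± 0.282 FPKM (SD, n = 2 each), FLT1 fell 3.01-fold and TEK 3.51-fold. The list median log2 fold change was -1.07 (camera adjusted p = 0.0104, and adjusted p = 0.701 with an estimated correlation), but without the expression filter the median was -0.05 and the call was lost (adjusted p = 0.0621). With voom the median was -1.72. Of 5 tested genes of smooth muscle and stroma, COL1A1 fell 8.56-fold, COL1A2 4.66-fold and ACTA2 from 4.07 to 2.85 FPKM, while TAGLN rose 4.36-fold and CNN1 1.70-fold (camera adjusted p = 0.539). Pluripotency genes were higher in 5, lower in 2 and not called in 3 of 10 tested members (median log2 fold change 0.18, camera adjusted p = 0.41). Among them TDGF1, a Nodal co-receptor, rose 8.20-fold, POU5F1 2.15-fold and SOX2 2.31-fold, and LEFTY2 fell 2.62-fold.

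Targets of BMP signalling were higher in 5 of 9 tested members, lower in 3 and not called in 1 (median log2 fold change 0.83, camera adjusted p = 0.41). ID4 rose 4.07-fold and ID2 3.55-fold, while MSX1 fell 25.4-fold and MSX2 4.29-fold. Of 5 tested genes of retinoic acid signalling and the posterior heart field, 3 fell and 2 rose (median log2 fold change -0.80, camera adjusted p = 0.667). HOXB1, a retinoic acid target of the posterior heart field, stood at 16.97 FPKM in WT and at 0 in SMYD1_KO, at least 236-fold lower against the floor of 3 reads per library. ALDH1A2, the main enzyme of retinoic acid synthesis in mesoderm, fell 15.7-fold, and NR2F2 rose 8.82-fold. The 5 lists of epicardium, neural ectoderm, neural crest, skeletal muscle and blood had fewer than 3 tested members and were given no list test. In these, BNC1 of the epicardium fell 17.6-fold, SNAI2 of the neural crest 18.4-fold and CKM of skeletal muscle 1.44-fold. The embryonic globin gene HBE1 of the blood list went from 53 and 68 reads in WT to 0 and 2 in SMYD1_KO. SIX3 of the neural ectoderm list went from 1 and 5 reads in WT to 711 and 714 in SMYD1_KO. OTX2, like SIX3 an anterior gene, rose 6.16-fold, and NGFR rose 3.91-fold. The call of CKM was lost without WT replicate 1 (adjusted p = 0.0769), WT replicate 2 (adjusted p = 0.131) or SMYD1_KO replicate 1 (adjusted p = 0.0839), and without the expression filter (adjusted p = 0.103).

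Transcriptional targets of Wnt/β-catenin signalling were mostly lower in SMYD1_KO. Of 14 tested members, 12 fell, 1 rose and 1 did not pass the test, also adjusted over the list alone. LEF1, itself a transcription factor of the pathway, fell from 37.0 ± 2.32 to 0.87 ± 0.22 FPKM (SD, n = 2 each; log2 fold change -4.35, SE 0.105, limma adjusted p = 1.42e-05). LGR5 fell 6.24-fold, NKD1 6.61-fold and MYC 4.66-fold. The 1 member that rose, named after its value was seen, was TNFRSF19, from 7.78 to 21.1 FPKM. The list had a median log2 fold change of -0.65 (camera adjusted p = 1.35e-04, and adjusted p = 0.455 with an estimated correlation), and of -1.18 with a mean of at least 5 FPKM. Several Wnt targets also mark mesoderm, and the endoderm markers rose in the same libraries by a median log2 fold change of 3.20.

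Genes that report ERK activity had no common direction. Of 18 members, 9 rose, 8 fell and 1 did not pass the test, also adjusted over the list alone. The immediate early genes EGR1 and FOS rose 4.99-fold and 4.77-fold, and PHLDA1 and the feedback inhibitor SPRY2 fell 13.4-fold and 2.38-fold. The list median log2 fold change was 0.23 and its mean -0.05, opposite in sign (camera adjusted p = 0.785). Transcripts of the pathway components themselves were higher in 3 of 14 members, lower in 3 and not called in 8, also adjusted over the list alone. GSK3B stood at 14.6 ± 1.43 FPKM in WT and 13.3 ± 1.10 FPKM in SMYD1_KO (SD, n = 2 each; limma adjusted p = 0.302). MAPK3, which encodes ERK1, fell 1.68-fold and CTNNB1, which encodes β-catenin, 1.22-fold, while AXIN1 rose 1.33-fold and GSK3A 1.28-fold. The call of CTNNB1 was lost without WT replicate 2 (adjusted p = 0.0515), SMYD1_KO replicate 1 (adjusted p = 0.062) or SMYD1_KO replicate 2 (adjusted p = 0.0949). That of GSK3A was lost without SMYD1_KO replicate 1 (adjusted p = 0.0644) or replicate 2 (adjusted p = 0.0948), and that of AXIN1 without SMYD1_KO replicate 2 (adjusted p = 0.071). The component list had a median log2 fold change of 0.02 and a mean of -0.02, and its median was below 0 with upper quartile or quantile scaling, with a mean of at least 5 FPKM and without SMYD1_KO replicate 1 (camera adjusted p = 0.785). Transcript levels do not measure the phosphorylation through which these kinases act.

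Genes of the cell cycle parted by phase. Of 20 members of the G2/M and mitosis list, 18 rose, none fell and 2 did not pass the test, also adjusted over the list alone. PLK1, a mitotic kinase, rose from 17.1 ± 1.18 to 35.6 ± 0.379 FPKM and FOXM1, a transcription factor of mitotic genes, from 15.6 ± 0.115 to 32.3 ± 1.13 FPKM (SD, n = 2 each). UBE2C rose 1.90-fold, and CENPF, which lies on 1q, 1.88-fold. The median log2 fold change was 0.63 (camera adjusted p = 3.34e-06, and adjusted p = 0.455 with an estimated correlation), and 0.59 without genes of 1q. Of 17 members of the G1/S and DNA replication list, 9 fell, 2 rose and 6 did not pass the test, with 9 lower and 3 higher adjusted over the list alone. PCNA, the DNA polymerase clamp, fell 1.65-fold, E2F1 1.67-fold and MCM6 1.52-fold, and RRM2 rose 1.51-fold. That list had a median log2 fold change of -0.32 (camera adjusted p = 0.045, and adjusted p = 0.701 with an estimated correlation). Its call was lost without WT replicate 2 (adjusted p = 0.113), SMYD1_KO replicate 1 (adjusted p = 0.0665) or SMYD1_KO replicate 2 (adjusted p = 0.0625), and with TMM scaling (adjusted p = 0.0587), voom on recovered reads (adjusted p = 0.0542) or a mean of at least 5 FPKM (adjusted p = 0.0699). Of 4 tested CDK inhibitor genes, CDKN1A, which encodes p21, fell from 15.3 ± 0.419 to 0.565 ± 0.126 FPKM (SD, n = 2 each). CDKN2D rose 3.83-fold and CDKN1C 1.59-fold, and CDKN1B did not pass the test. The median log2 fold change of these 4 genes was 0.36 and the mean -0.37, opposite in sign (camera adjusted p = 0.667).

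**Figure D2:**
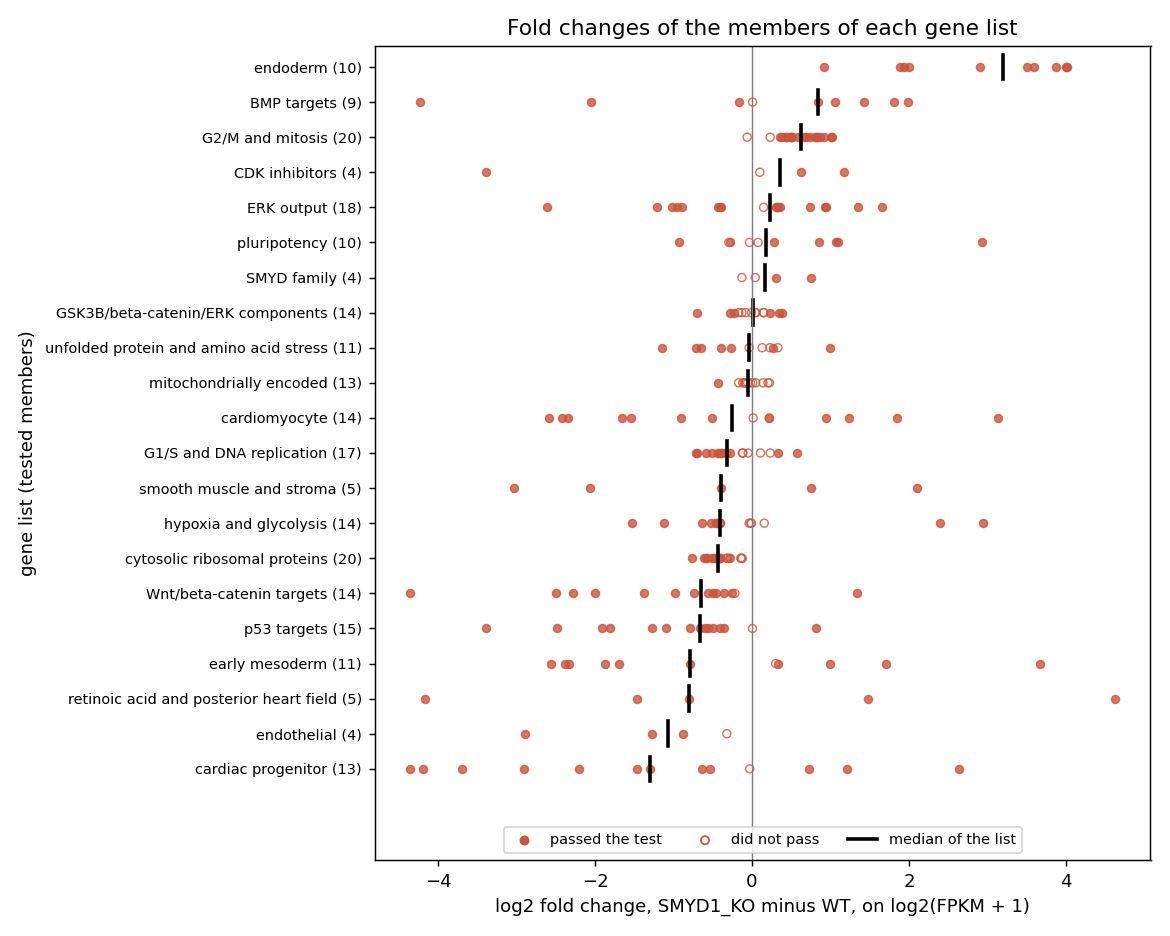
Log2 fold change (SMYD1_KO minus WT, on log2(FPKM + 1)) of each tested member of the 21 gene lists with at least 3 tested members; filled circles passed the test, open circles did not, and black bars are list medians. Endoderm lies highest with a median of 3.20 and cardiac progenitor lowest with -1.29.

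Targets of the transcription factor p53 were lower in SMYD1_KO in 13 of 15 tested members, with 1 higher and 1 not called, also adjusted over the list alone. Besides CDKN1A, PHLDA3, which lies on 1q, fell 9.96-fold, the stress cytokine gene GDF15 fell 12.6-fold and the death receptor gene TNFRSF10B 3.89-fold. The 1 member that rose, named after its value was seen, was BTG2 on 1q, from 18.4 to 33.2 FPKM. The list had a median log2 fold change of -0.67 (camera adjusted p = 1.41e-04, and adjusted p = 0.455 with an estimated correlation). Genes of the unfolded protein and amino acid response were lower in 5, higher in 2 and not called in 4 of 11 members, with ASNS down 2.24-fold, TRIB3 down 1.82-fold, HERPUD1 down 1.69-fold and ATF3, on 1q, up 2.67-fold (median log2 fold change -0.04, camera adjusted p = 0.539). The call of ATF3 was lost without SMYD1_KO replicate 1 (adjusted p = 0.0596). Hypoxia and glycolysis genes were lower in 7, higher in 2 and not called in 5 of 14 tested members, with 8 lower adjusted over the list alone (median log2 fold change -0.40, camera adjusted p = 0.265). ADM and VEGFA, which encode secreted vascular factors, rose 8.81-fold and 5.64-fold, and PDK1 and PFKFB4 fell 3.89-fold and 2.80-fold.

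Cytosolic ribosomal protein genes were lower in SMYD1_KO in 14 of 20 members and none was higher, with 16 lower adjusted over the list alone. RPS23 fell 1.78-fold, RPS3 1.53-fold and RPL5 1.51-fold, and each has processed pseudogenes with which reads can be shared. The median log2 fold change was -0.43 (camera adjusted p = 1.47e-04, and adjusted p = 0.701 with an estimated correlation). These genes took 3.93% and 4.38% of reads in the WT libraries and 2.97% and 3.4% in the SMYD1_KO libraries, so libraries of 1 group differed as well. Of 13 mitochondrially encoded genes, MT-CO3 alone passed the test and fell 1.35-fold, and none passed adjusted over the list alone (median log2 fold change -0.05, camera adjusted p = 0.652). The call of MT-CO3 was lost on leaving out any 1 of the 4 libraries, with adjusted p = 0.0975 without WT replicate 1, 0.131 without WT replicate 2, 0.173 without SMYD1_KO replicate 1 and 0.191 without SMYD1_KO replicate 2. It was also lost without the expression filter (adjusted p = 0.274).

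Among the annotation terms of the deposited table, the cytosolic large ribosomal subunit was lower in SMYD1_KO, with 39 of its 104 tested genes lower, 1 higher and a median log2 fold change of -0.32 (camera adjusted p = 0.00229). No term was called with an estimated correlation, where few residual degrees of freedom remain. No other term passed among 353 cellular components, 424 molecular functions and 1491 biological processes. With a one-sided Fisher's exact test of the called genes, higher and lower together, 28, 27 and 131 terms passed. The cytosolic large ribosomal subunit was not among them (unadjusted Fisher p = 0.992). That test ignores direction, and 49.8% of all tested genes were called. The number of terms called by camera also depended on single libraries, at 11 without WT replicate 1, 2 without WT replicate 2, 0 without SMYD1_KO replicate 1 and 19 without SMYD1_KO replicate 2.

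Genes were also compared by autosome, since edited clones of pluripotent lines can differ in copy number. Genes of 1q were higher in SMYD1_KO in 82.7% of 649 tested genes, with a median log2 fold change of 0.495, and 424 were called higher and 62 lower. Genes of the short arm, 1p, had a median of -0.003 over 799 tested genes, and those of the other autosomes a median of 0.003. Chromosome 1 was the 1 autosome whose genes passed the test as a set (camera adjusted p = 0.00218). By arm, a test added after the chromosome values were seen, 1q had an unadjusted camera p of 1.41e-14, and p = 0.0144 with an estimated correlation. Without genes of 1q, 6388 genes were called, 3172 higher and 3216 lower, and 8 lists passed, as many as with all genes.

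**Figure D3:**
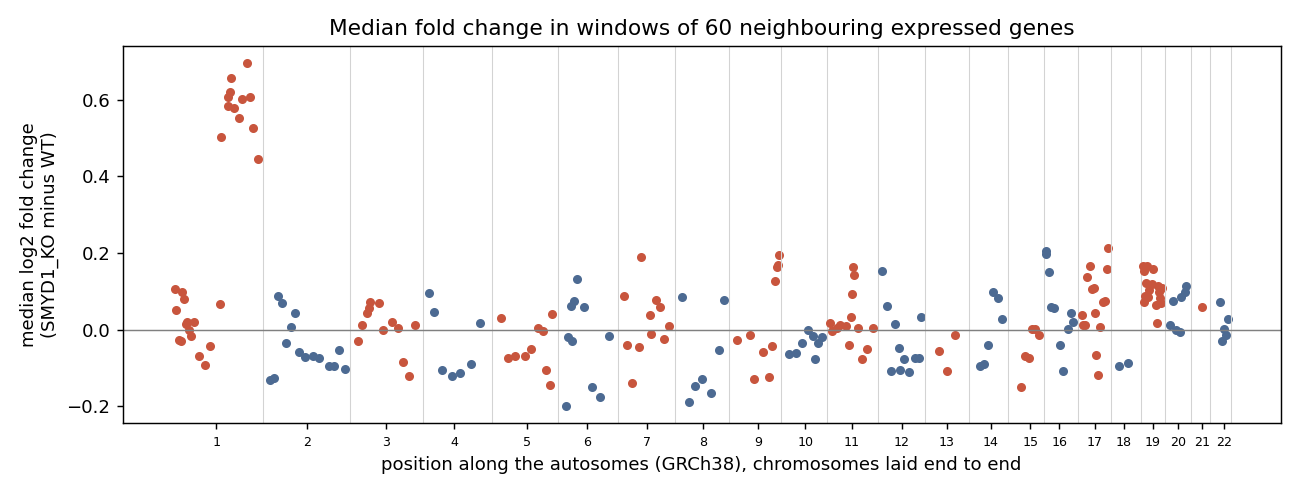
Median log2 fold change (SMYD1_KO minus WT) in windows of 60 neighbouring genes with a mean of at least 5 FPKM, along the autosomes in GRCh38, with neighbouring chromosomes in alternating colours and each point 1 window. The 11 windows within 1q lie between 0.445 and 0.695, and windows without genes of 1q lie between -0.2 and 0.212.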

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

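The tests outside 1q were chosen after the chromosome values were seen; the other alternatives were chosen before. All 105 named genes tested or fitted kept their sign under every alternative in which they were present, and 1 autosome was called in each except outside 1q (0), by its construction. With a mean of at least 5 FPKM, which tests fewer genes, 4320 genes were called (2339 higher, 1981 lower in SMYD1_KO), and 5 lists and 9 terms passed. Cardiac progenitor (-0.91, camera adjusted p = 0.153) and G1/S (-0.33, camera adjusted p = 0.0699) did not pass there. The endothelial list then had fewer than 3 tested members and was not tested. With a 2-fold minimum 1925 genes remained called (1029 higher, 896 lower). G1/S also missed the threshold with TMM scaling (-0.33, adjusted p = 0.0587) and voom (-0.40, adjusted p = 0.0542); the cause was not tested. Leaving out each library, where a lone library is assumed to vary like the other group, gave 4602 to 5649 called genes, 2171 to 2642 lower genes, 0 to 19 terms and G1/S medians from -0.35 to -0.28, with fewer samples. Against 8 lists called, camera with an estimated correlation called 0 and fry, which tests another question, called 15. The former has few residual degrees of freedom with 4 libraries. The 1 term called became 2 with a pseudocount of 0.1, 6 without a filter, 2 with upper quartile scaling, 4 with quantile normalization, 7 with voom, 4 outside 1q and 186 by Fisher's exact test; the cause was not tested. Replicate numbers were shared between groups without a stated pairing. The correlation of same-numbered deviations was 0.144 over only 2 pairs. With the replicate block 8048 genes were called (4154 higher, 3894 lower) and 10 terms, no gene named in the text and no list changed its call, and SMYD1 kept its log2 fold change of -0.70. SMYD1 was at -1.17 with a pseudocount of 0.5, -2.86 with 0.1 and -6.63 with voom. Among lists that were not called, medians also moved with the filter: CDK inhibitors were at 0.03 without it and 0.10 at 5 FPKM, retinoic acid at -0.23 and the SMYD family at 0.04 without it, pluripotency at 0.08 and 0.57, smooth muscle and stroma at -0.16 and -0.65, and hypoxia at -0.03 at 5 FPKM. The unfolded protein list was at -0.27 at 5 FPKM and at 0.02, of opposite sign, without WT replicate 1. Mitochondrially encoded genes were at -0.12 with upper quartile scaling and 0 with quantile normalization. Voom on recovered reads called 7701 genes, of which 6658 were also called by the FPKM test. Upper quartile scaling moved the share of higher calls from 52.2% to 45.4%, quantile normalization to 49.1% and leaving out genes of 1q to 49.7%, so lower calls were then the more numerous. Depth limits SMYD1 itself, at 54 and 47 reads in WT, and other genes near 1 FPKM.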

Other observations

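The epithelial, mesenchymal and HOX lists were added after the fixed lists had been seen. Epithelial genes were higher in SMYD1_KO in 11 of 14 tested members, lower in 1 and not called in 2, with a median log2 fold change of 2.32 (camera adjusted p = 2.80e-05, and adjusted p = 0.0898 with an estimated correlation). CDH1, which encodes E-cadherin, went from 12.5 to 79.99 FPKM, EPCAM from 22.3 to 162.5 FPKM, and the splicing regulator ESRP1 from 4.08 to 34.9 FPKM. Mesenchymal genes were lower in 8 of 11 tested members, higher in 2 and not called in 1 (median -1.26, camera adjusted p = 0.00207, and adjusted p = 0.0898 with an estimated correlation). VIM, which encodes vimentin, went from 89.4 to 6.32 FPKM and CDH11 from 48.7 to 3.01 FPKM, while CDH2, which encodes N-cadherin, rose from 44.6 to 176 FPKM.

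Among HOX genes, HOXB1 and HOXB2, also named above, fell together with HOXB3, which went from 8.03 to 0.084 FPKM. The HOX list test was computed but is not used, since HOXB1 had been seen to fall before the list was written. HOXB4 and HOXB5, below the filter, had 1.59 and 1.10 FPKM in WT and 0 in SMYD1_KO. The anterior genes SIX3 and OTX2 and the retinoic acid degrading enzyme gene CYP26A1 rose in the same libraries.

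Of the tests below, those of the differentiation run, MDM4, the extra copy of 1q and the clones, and the second endoderm list without CXCR4 and HHEX, were chosen after the result was seen. For endoderm genes, which rose while HAND1, PDGFRA and BMP4 fell, the explanations weighed were these. Differences between the scalings tried were too small a source, since the median of all tested genes stayed between -0.041 and 0.012. The endoderm median log2 fold change was at least 3.14 under them, an outcome that those small shifts fixed in advance. Direct dosage of whole chromosomes was too small a source, since autosome medians lay between -0.106 and 0.206. Subtracting each member's chromosome median left 3.12, an outcome that those small medians fixed in advance. An indirect effect of copy number was not tested. A definitive endoderm state of SMYD1_KO cells is a candidate explanation that was not tested separately. In a second endoderm list 10 of 12 tested genes rose and 2 fell, with a median of 1.60 (camera adjusted p = 1.41e-04, and adjusted p = 0.0898 with an estimated correlation). That list extends the rise to other genes of the same libraries, and does not show its cause or the share of cells involved. Without CXCR4 and HHEX, which are among the largest increases, the median of the other 10 genes was 1.54 (unadjusted camera p = 0.0017, and p = 0.0819 with an estimated correlation). A different differentiation run or plate cannot be told apart from the genotype, since the labels name 0 runs.

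For the fall of p53 targets, the scalings tried left the median log2 fold change at -0.65 or lower, which their small shifts of all genes also fixed in advance. A second list of p53 targets had a median of -0.39, with 17 of 28 tested genes lower and 3 higher (camera adjusted p = 2.83e-04, and adjusted p = 0.0898 with an estimated correlation). Among all 13902 tested genes, 3309 were lower. The second list extends the fall to other targets in the same libraries. Lower p53 activity in the SMYD1_KO cells is a candidate explanation that was not tested separately. A part of MDM4, a p53 inhibitor on 1q, cannot be told apart from the shift of 1q, since its log2 fold change of 0.79 (SE 0.15, adjusted p = 0.00981) was to be expected where 82.7% of tested 1q genes were higher; lowering MDM4 in SMYD1_KO cells would test it. MDM2, itself a member of the first p53 list, did not fall, at 3.27 FPKM in both groups (limma adjusted p = 0.97). Neither p53 activity nor DNA copy number was measured directly.

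The shift of 1q was weighed last. A few strongly changed genes are argued against as its source, since 82.7% of tested 1q genes were higher. The median log2 fold change of 0.50 on 1q against -0.003 on 1p is consistent with an extra copy of 1q in most SMYD1_KO cells, a hypothesis that DNA would test. Whether clones or lines differed before the edit cannot be told apart from an effect of editing or of culture, since the labels name 0 clones or passages. No difference in these data can therefore be assigned to SMYD1 alone.

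At the SMYD1 locus, the 6 tested genes within 1 Mb had a median log2 fold change of 0.10 but moved in both directions. THNSL2 (-0.94) and RPIA (-0.59) fell, EIF2AK3 (0.82) and FOXI3 (0.37) rose, and KRCC1 and AC093616.4 did not pass the test. Of 16 cardiac genes within 5-fold of the WT level of SMYD1, 1, TBX5, was at 0 reads in SMYD1_KO. PLN, IRX4 and NPPA, named after their values were seen, went from 32, 48 and 114 reads over the WT libraries to 2, 4 and 13 reads over the SMYD1_KO libraries, so steep falls were not limited to SMYD1 and TBX5. These were the steepest after TBX5. Other falls among the 16 genes ranged from 1.39-fold (MYH7) to 4.99-fold (MYOM1), and NKX2-5, TTN and LDB3 were higher in SMYD1_KO.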
